A study of Sus scrofa domesticus with 6 samples.

How the data were processed

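Condyles of the lower jaw of miniature pig embryos were sampled at 45 and 85 days, 3 libraries per age. Per the labels' protocols, tissue was ground in liquid nitrogen, total RNA was extracted with an RNeasy kit, ribosomal RNA was removed with magnetic beads, and the second cDNA strand was degraded, which keeps the strand of the RNA. HISAT2 is named in the submitters' processing notes, without a version. The counting program, its strand setting, the genome build and the annotation release are not given in the sources used here. The proteome that the series title mentions was not analysed here.

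The authors deposited a single table with whole-number read counts per gene and, beside them, FPKM values for the same libraries, per the file headers. Its 25322 rows carry Ensembl pig gene IDs and include no row without a gene. For 10748 genes with at least 50 counts, the deposited FPKM equalled the count divided by the library's total count and by a factor per gene. That factor was the same in all libraries, with a largest relative deviation of 0.0015%, and was not compared with gene lengths. The FPKM values therefore add a factor per gene, presumably its length, and library totals to the counts, and no further normalization between libraries. Gene names came from the table for 16162 rows and from a table of IDs and symbols for 1774 more, and 7386 rows have no name. Where several IDs share a symbol, the ID with the highest counts carries it and 2200 rows are known by ID only. No row was named COL1A1, so this gene is not reported here. Total counts ran from 12546729 to 16559616, so 1 count is worth less than 0.1 CPM and levels near or below 1 CPM rest on few counts.

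Samples were grouped by the age in their titles. Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by age with its default minimum count of 10, TMM normalization, robust dispersion estimates and the quasi-likelihood F test, with age as the only factor. The standard error of a log2 fold change is its size divided by the square root of F. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are TMM-normalised CPM. PRG4, the lubricin gene, did not pass the filter, with 7, 2 and 559 counts in the day 45 libraries and 4, 35 and 10 in the day 85 libraries, and was not tested.

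Before the data were examined, 36 gene lists with 835 entries were fixed for cartilage, bone, signalling, and the other cell types a dissected condyle could hold, and 35 had the minimum of 5 tested members. Of the entries, 115 matched no row. A list of sex-linked genes had 2 tested members and was not tested as a list; neither passed. Each list was tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists; camera with an estimated correlation and fry were run beside it. Camera called 12 lists higher and 8 lower with the preset correlation and 0 and 0 with an estimated one. Fry, which tests whether the genes of a list move on balance in 1 direction, called 4 higher and 2 lower. Gene Ontology and KEGG terms in the table, with 10 to 500 annotated tested genes, were tested with a one-sided Fisher's exact test on called genes with at least a 2-fold change, each direction apart.

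The genes named in the text followed a rule fixed in advance. It took 17 anchor genes of cartilage, bone and resorption, of which 15 could be tested. It added the 10 named genes with the largest rise and the 10 with the largest fall among called genes whose ages did not overlap and whose higher age averaged at least 10 CPM. For each list it took up to 4 called members with the largest change and at least 1 CPM or, where fewer than 2 were called, the 2 most abundant members. Where 1 member was called it is named too, a choice made after its values were seen. A few genes that the rule selects are not reported here.

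The test was tried on data simulated for the comparison of day 85 with day 45, 3 libraries each, in 10 simulations with 200 changed genes. It recovered 12.6% of genes changed 2-fold and 80.2% of those changed 4-fold, and 8.38% of its calls were false. Fewer genes were changed than the 986 called in the data, which affects the adjusted p, so these shares need not hold there. A planted list was called in 10 of 10 simulations and 0 of 350 unchanged lists were. Genes were simulated independently, so these lists lacked the inter-gene correlation estimated in the data, such as 0.773 for osteoclast and 0.637 for cell cycle. The simulation therefore does not show how often camera with the preset correlation calls unchanged lists of correlated genes. No pair of libraries was a duplicate: over genes with at least 10 counts, the chi-square per degree of freedom was 20.2 or more in every pair.

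Alternatives fixed in advance were RLE, upper-quartile and total-count scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the deposited FPKM plus 1 with and without a minimum FPKM of 1 in 3 libraries and on FPKM plus 0.1 with it, a test against a 1.5-fold change, leaving out the 20 most abundant genes, the replicate number as a block, and leaving out each library. Leaving out the 37 genes of the mitochondrial genome and adding a skeletal muscle score, the mean log2 CPM of the muscle list, as a covariate, for lists with the preset and with an estimated correlation, were chosen after seeing the data. Data preparation used Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.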

Results

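The mandibular condyle, the growing end of the lower jaw that forms its side of the temporomandibular joint, was profiled by RNA sequencing in miniature pig embryos at 45 and 85 days of gestation. The series compares the ages to follow ossification of the condylar cartilage. Each age has 3 libraries, made from total RNA after removal of ribosomal RNA. The deposited table gives counts for 25322 gene rows. Total counts per library were 16559616, 14336583 and 14221365 at day 45 and 12546729, 16033822 and 15287641 at day 85, and 4871 rows had no count in any library. The labels do not say that all libraries come from separate animals, so p-values measure the spread between these libraries only. All fold changes are day 85 over day 45, with n = 3 libraries per age, levels are normalised counts scaled to library size (CPM) as mean ± SD, and adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

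At day 85 the condyle libraries held lower levels of cartilage matrix and cell cycle genes than at day 45, and higher levels of vessel, antigen presentation and osteoclast genes, each tested as a list by camera with a preset correlation. With an estimated correlation camera called 0 lists. Fry called the cell cycle, endothelial and interferon lists (adjusted p = 0.0338, 0.0414 and 0.0338). It left cartilage matrix at an adjusted p of 0.0832 and osteoclast at 0.150. Of 15022 genes tested, 586 were higher and 400 lower at day 85, and 425 and 203 of these changed at least 2-fold. In all 986 genes the 3 libraries of one age lay above the 3 of the other, which held for 35.03% of all tested genes and for 10% by chance. With library totals alone as the scaling, 437 genes were higher and 598 lower, so the share of rises depends on the scaling. These counts rest on few libraries. They became 4, 0 and 20 without day 45 replicates 1, 2 and 3, and 16, 3412 and 118 without day 85 replicates 1, 2 and 3, by edgeR. In the fit that left 0 genes, 3056 had an unadjusted p under 0.05, against 4367 with all libraries. Of the 85 named genes that were called, 85 kept the call without day 85 replicate 2 and 0 to 17 without each of the others.

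The day 85 libraries were not alike. The first principal component, with 50% of the variance, separated the ages, and the second, with 26.6%, set day 85 replicate 2 (-76.74) apart from replicates 1 (20.35) and 3 (20.47). Across genes, Spearman's rho was 0.980 between day 85 replicates 1 and 3 but 0.931 and 0.938 between replicate 2 and these, and 0.939 between replicate 2 and each day 45 library; the day 45 libraries correlated at 0.975 to 0.984. Genes of a skeletal muscle list took 5.65%, 0.337% and 4.52% of the counts of day 85 replicates 1, 2 and 3, against 1.17%, 0.575% and 1.51% at day 45. ACTA1, the actin of skeletal muscle fibres, stood at 8543, 714 and 7325 CPM in the day 85 libraries.

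**Figure D1:**
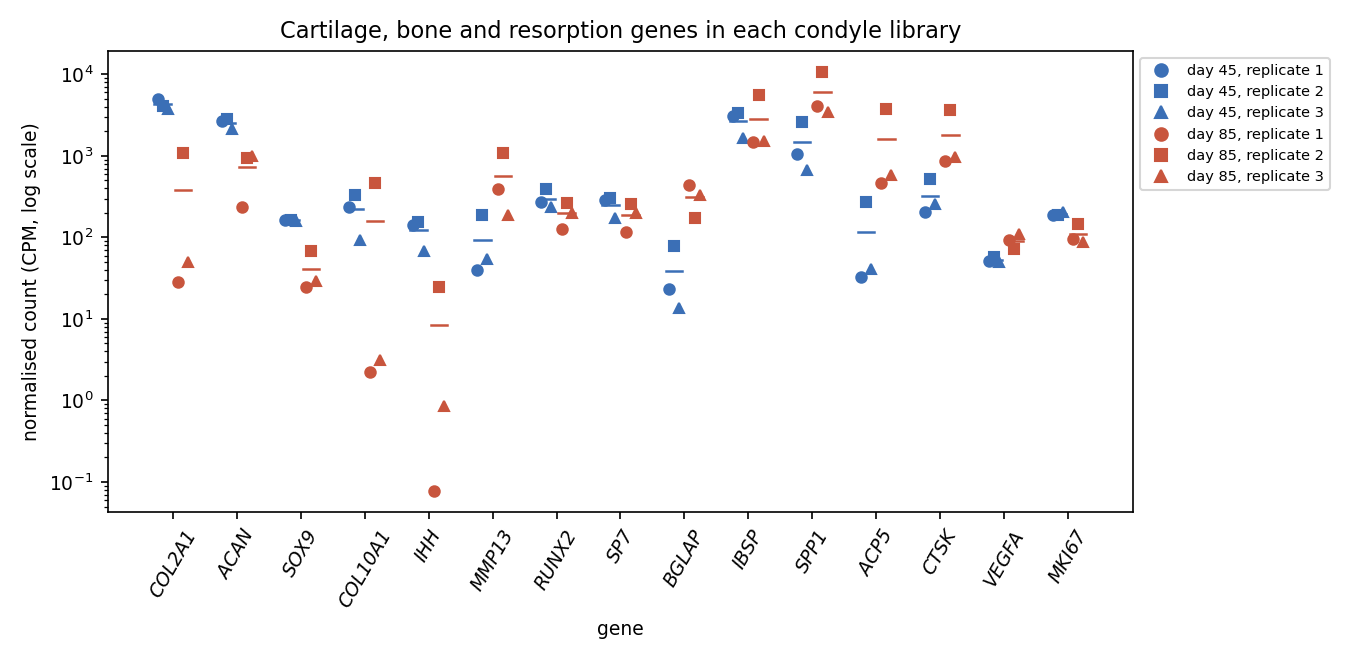
Normalised counts (CPM, log axis) of the 15 anchor genes that could be tested, in each library. Blue marks are day 45, red marks day 85, the marker shape gives the replicate and the short lines are group means (n = 3). COL2A1 stands at 28.8, 1074 and 50.6 CPM in the day 85 libraries against a day 45 mean of 4280, and COL10A1 and IHH show the same split, with day 85 replicate 2 highest.

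Cartilage matrix genes fell as a list. HAPLN1, which links aggrecan to hyaluronan, fell 6.90-fold from 1280 ± 197 to 186 ± 122 CPM (log2 fold change -2.79, SE 0.50, adjusted p = 0.0353). CHADL, a chondroadherin-like cartilage protein, fell 7.88-fold (adjusted p = 0.0321), and the fibrillar collagen COL11A1 fell 2.60-fold from 4256 ± 490 CPM (adjusted p = 0.0458). The small proteoglycan EPYC also fell (adjusted p = 0.0487), at the low level of 1.95 CPM at day 45. Of the 19 members tested, these 4 fell and none rose, 8 fell when adjusted over the list alone, and 16 had a negative log2 fold change, with a median of -2.58. The list's camera adjusted p was 1.23e-06, and adjusted p = 0.535 with an estimated correlation. COL2A1, the main collagen of cartilage, had the log2 fold change -3.48 with an SE of 1.41 and did not pass (adjusted p = 0.168), and ACAN, the core protein of aggrecan, had -1.83 with an SE of 0.53 (adjusted p = 0.0865). Without day 85 replicate 2, 13 members fell and COL2A1 passed at a log2 fold change of -6.75 (adjusted p = 0.000394), with HAPLN1, CHADL and EPYC at -3.45, -3.78 and -4.63; without each of the other 5 libraries 0 members passed in edgeR, with 8 or 9 lower and 0 or 1 higher at an unadjusted p under 0.05. DESeq2 on all libraries called 12 lower and 1 higher.

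Among the regulators of chondrocyte identity, SOX9, the master transcription factor of the cartilage lineage, fell 3.98-fold from 161 ± 2.99 to 40.5 ± 23.5 CPM (log2 fold change -1.99, SE 0.39, adjusted p = 0.0400). It lies on chromosome 12 at 9027639 to 9033210 in the coordinates of the deposited table, whose genome build is not given in the sources used here. SOX9 was the 1 of 14 members past the threshold, and 3 fell when adjusted over the list alone; the list as a whole was lower (camera adjusted p = 0.00654; adjusted p = 0.535 with an estimated correlation). PTH1R, the receptor for parathyroid hormone-related protein, stood at 685 ± 182 and 307 ± 142 CPM and WWP2 at 411 ± 54.1 and 124 ± 70.8 CPM, neither past the threshold. The SOX9 call held without day 85 replicate 2 (adjusted p = 0.000295) but was lost without any other library, where adjusted p ran from 0.0823 to 0.145. In the list, 6 members fell without day 85 replicate 2 and 0 without each of the others in edgeR, and DESeq2 on all libraries called 5 lower.

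Genes of hypertrophic chondrocytes did not move as a list. Its camera adjusted p was 0.884, with the test pointing down while the median and mean log2 fold changes were 0.09 and 0.01. COL10A1, the collagen of hypertrophic cartilage, stood at 221 ± 121 CPM at day 45 and at 2.24, 466 and 3.16 CPM in the day 85 libraries (log2 fold change -0.49, SE 1.80, adjusted p = 0.880). IHH, the hedgehog ligand of prehypertrophic cells, stood at 122 ± 47.0 CPM and then at 0.0773, 24.6 and 0.857 CPM (adjusted p = 0.157). The collagenase MMP13 was at 94.3 ± 82.4 and 562 ± 476 CPM (adjusted p = 0.122). The angiogenic factor VEGFA was the 1 of 14 members that passed, rising 1.72-fold from 53.0 ± 3.89 to 91.1 ± 18.9 CPM (adjusted p = 0.0465). Adjusted over the list alone, 2 rose and 1 fell. Without day 85 replicate 2, 3 members rose and 4 fell, the median was -0.20, and COL10A1 passed at a log2 fold change of -6.33 (adjusted p = 0.00399). VEGFA passed without that library too (adjusted p = 0.00515) and lost its call without each of the others, with adjusted p from 0.111 to 0.184.

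Of 22 bone matrix and osteoblast genes, 0 passed the test in edgeR, over all genes or adjusted over the list alone. COL1A2, a chain of type I collagen, was at 36513 ± 6805 CPM at day 45 and 50453 ± 12570 CPM at day 85 (log2 fold change 0.47, SE 0.26, adjusted p = 0.276), and COL5A1 at 4728 ± 457 and 4219 ± 1534 CPM (adjusted p = 0.732). RUNX2 and SP7, the transcription factors of osteoblast differentiation, had log2 fold changes of -0.60 and -0.42 with SEs of 0.30 and 0.34 (adjusted p = 0.239 and 0.447). The sialoprotein IBSP was at 2710 ± 928 and 2847 ± 2314 CPM (adjusted p = 0.951). BGLAP, which encodes osteocalcin, had a log2 fold change of 3.04 with an SE of 0.74, from 38.5 ± 34.6 to 317 ± 136 CPM, and did not pass (adjusted p = 0.0627); osteopontin, SPP1, had 2.06 with an SE of 0.67 (adjusted p = 0.111). The list's median was -0.17 and its mean 0.04, with a camera adjusted p of 0.811 in the downward direction. At an unadjusted p under 0.05, 2 were higher and 2 lower. DESeq2 called 2 members higher and 2 lower, and without day 85 replicate 2 edgeR called 1 higher and 4 lower, BGLAP among the former at adjusted p = 0.0300.

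Osteocyte genes split. SOST, the secreted Wnt inhibitor sclerostin, fell 5.07-fold from 66.7 ± 13 to 13.2 ± 3.12 CPM (log2 fold change -2.34, SE 0.23, adjusted p = 0.0160). KERA, a corneal and tendon proteoglycan, fell 4.83-fold (adjusted p = 0.0405) and PDPN, podoplanin, fell 2.31-fold (adjusted p = 0.0259). These 3 were the members past the threshold among 13, none rose over all genes, and adjusted over the list alone 3 fell and 2 rose. The list did not pass as a whole (camera adjusted p = 0.0860), though it did without day 45 replicate 3 (0.0242) and without day 85 replicate 2 (0.0190), where 5 members fell and 1 rose; leaving out each of the other libraries left 0 or 1 that fell. DESeq2 called 4 lower and 2 higher. Of 15 genes of mineralization and phosphate handling, 0 passed in edgeR, also adjusted over the list alone, while 5 were higher and 2 lower at an unadjusted p under 0.05. DESeq2 was run on all genes with a count. It called 5 higher and 2 lower of 17 members, counted whether or not they got an adjusted p. Without day 85 replicate 2, edgeR called 1 higher and 2 lower. That list did not pass (camera adjusted p = 0.411).

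Osteoclast genes were higher as a list. All 19 tested members had a positive log2 fold change, with a median of 2.47, and the list's camera adjusted p was 2.98e-06 (adjusted p = 0.535 with an estimated correlation). STRIP2 was the 1 member past the threshold over all genes, at 12.2 ± 3.35 and 40.6 ± 3.10 CPM (adjusted p = 0.0181), whereas 13 rose when adjusted over the list alone. CTSK, the collagen-degrading cathepsin K, had a log2 fold change of 2.47 with an SE of 0.69 (adjusted p = 0.0841), ACP5, the tartrate-resistant acid phosphatase, 3.79 with an SE of 1.26 (adjusted p = 0.119), and the gelatinase MMP9 3.59 with an SE of 1.42 (adjusted p = 0.1604). ACP5 stood at 469, 3721 and 586 CPM in the day 85 libraries and averaged 115 ± 136 CPM at day 45. CTSK and MMP9 also peaked in day 85 replicate 2. STRIP2 did not, at 43.4, 37.3 and 41.2 CPM, so the 1 called member did not follow these genes between libraries. Without day 85 replicate 2, 5 members rose and the median was 1.65. Without each of the others in turn, 0 or 1 rose, with 4 to 19 higher at an unadjusted p under 0.05 and a median of 2.25 to 2.97. DESeq2 on all libraries called 11 higher.

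**Figure D2:**
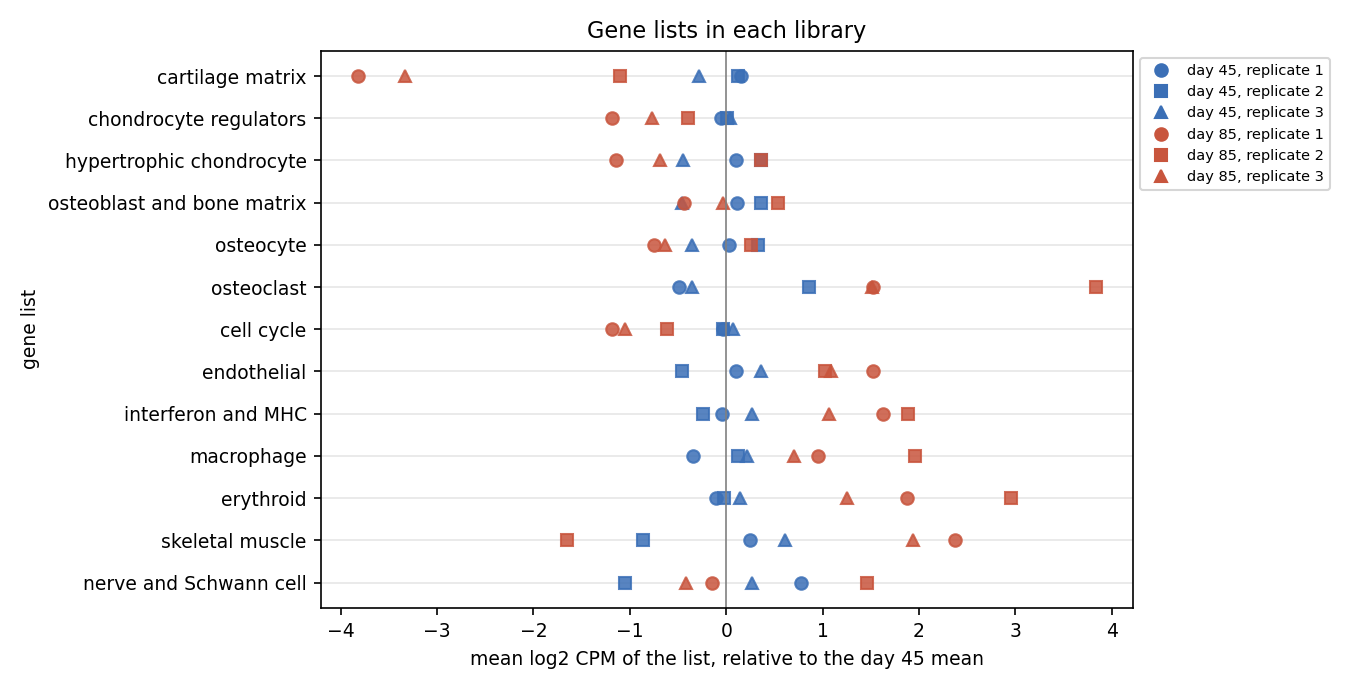
Mean log2 CPM of 13 gene lists in each library, relative to the mean of the day 45 libraries (line at 0). Blue marks are day 45, red marks day 85, and the marker shape gives the replicate. Cartilage matrix stands at -3.82, -1.10 and -3.33 in day 85 replicates 1, 2 and 3, osteoclast at 1.52, 3.84 and 1.51, and skeletal muscle at 2.37, -1.65 and 1.94.

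Cell cycle genes were lower at day 85 throughout. All 32 tested members had a negative log2 fold change, with a median of -0.95, 16 fell over all genes, and 31 fell when adjusted over the list alone. KIF11, a mitotic kinesin, fell 2.28-fold from 46.8 ± 4.15 to 20.5 ± 2.03 CPM (log2 fold change -1.19, SE 0.13, adjusted p = 0.0167). TYMS, which makes thymidylate for DNA synthesis, fell 2.43-fold (adjusted p = 0.0219), CENPE, a centromere motor, 2.39-fold (adjusted p = 0.0287) and the mitotic cyclin CCNB1 2.30-fold (adjusted p = 0.0379). MKI67 had a log2 fold change of -0.83 with an SE of 0.20 and lay just outside the threshold (adjusted p = 0.0566). The list's camera adjusted p was 4.59e-18, and adjusted p = 0.494 with an estimated correlation. Without day 85 replicate 2, 31 members fell; without each of the other libraries, 0 did in edgeR, although 30 had an unadjusted p under 0.05 and the median lay between -0.99 and -0.83. DESeq2 on all libraries called 30.

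Endothelial genes rose. VWF, the von Willebrand factor, rose 6.40-fold from 15.8 ± 5.80 to 101 ± 16.4 CPM (log2 fold change 2.68, SE 0.29, adjusted p = 0.0160), MMRN2 rose 3.85-fold (adjusted p = 0.0443), the junction protein PECAM1 3.15-fold (adjusted p = 0.0362) and the VEGF receptor FLT1 3.13-fold (adjusted p = 0.0432). In all, 10 of 19 members rose and none fell, 16 rose when adjusted over the list alone, and the median log2 fold change was 1.2 (camera adjusted p = 1.90e-09; adjusted p = 0.535 with an estimated correlation). Of 12 mural and smooth muscle cell genes, RGS5 rose 3.65-fold (adjusted p = 0.0386) and MCAM 2.24-fold (adjusted p = 0.0200), whereas CSPG4, a proteoglycan of pericytes and of cartilage progenitors, fell 2.04-fold (adjusted p = 0.0491). Adjusted over the list alone, 5 rose and 1 fell, and the list was higher (camera adjusted p = 0.00176; adjusted p = 0.535 with an estimated correlation), though its level in day 85 replicate 2 lay within the day 45 range. Without day 85 replicate 2, 14 endothelial genes rose, and 6 mural genes rose and 1 fell. Without each of the others in turn, 0 to 2 endothelial and 0 mural genes passed. In those fits 14 to 16 endothelial genes were higher at an unadjusted p under 0.05, with a median of 0.99 to 1.39. DESeq2 on all libraries called 16 endothelial genes higher, and 5 mural genes higher and 1 lower.

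Genes of interferon response and antigen presentation rose. SLA-DRA, the alpha chain of swine MHC class II, rose 10.2-fold from 15.1 ± 7.07 to 154 ± 39.9 CPM (log2 fold change 3.35, SE 0.38, adjusted p = 0.0181), and SLA-DQA rose 6.26-fold (adjusted p = 0.0219). The interferon-induced GTPases MX2 and MX1 rose 7.22-fold and 5.73-fold (adjusted p = 0.0181 and 0.0383), from 0.995 and 2.29 CPM. In all, 10 of 19 members rose, none fell, and 15 rose when adjusted over the list alone, with a median log2 fold change of 1.45 (camera adjusted p = 1.79e-09; adjusted p = 0.494 with an estimated correlation). Reads of SLA genes may be split between near-identical family members, so their single values are uncertain. Without day 85 replicates 2 and 3 in turn, 10 and 6 members rose; without each of the other 4 libraries, 0 or 1 did.

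Macrophage genes were higher as a list, with 4 of 17 past the threshold upward and none downward. These were the scavenger receptor MSR1, 4.09-fold up (adjusted p = 0.0287), and the complement genes C1QC, C1QB and C1QA, which rose 3.24-fold, 3.08-fold and 2.49-fold (adjusted p = 0.0238, 0.0383 and 0.0480). Adjusted over the list alone, 12 rose and 1 fell (camera adjusted p = 2.73e-05; adjusted p = 0.535 with an estimated correlation). Among 13 erythroid and megakaryocyte genes, SLC4A1, the anion exchanger of red cells, rose 27.7-fold from 0.957 CPM to 23.0, 47.1 and 10.6 CPM in the day 85 libraries (adjusted p = 0.0379), and the transcription factor KLF1 (adjusted p = 0.0363) rose from a very low level. KLF1 had 1 count at day 45 and 168 at day 85, a ratio of 177 with a 95% counting interval of 31.4 to 7040, which leaves out the spread between libraries (2.16, 8.13 and 1.19 CPM at day 85). The log2 fold change of SLC4A1 was 4.79, and 4.11 without day 85 replicate 2 (adjusted p = 0.0138) or 6.06 without day 45 replicate 3 (adjusted p = 0.0591). Adjusted over the list alone, 10 rose (camera adjusted p = 0.000204; adjusted p = 0.535 with an estimated correlation). Without day 85 replicate 2, 9 macrophage genes rose and 1 fell; without each of the others in turn, 0 to 2 rose. In the erythroid list 6 genes rose without day 85 replicate 2 and the list's median log2 fold change was 1.81 rather than 2.79; without each of the others, 0 or 1 rose.

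**Figure D3:**
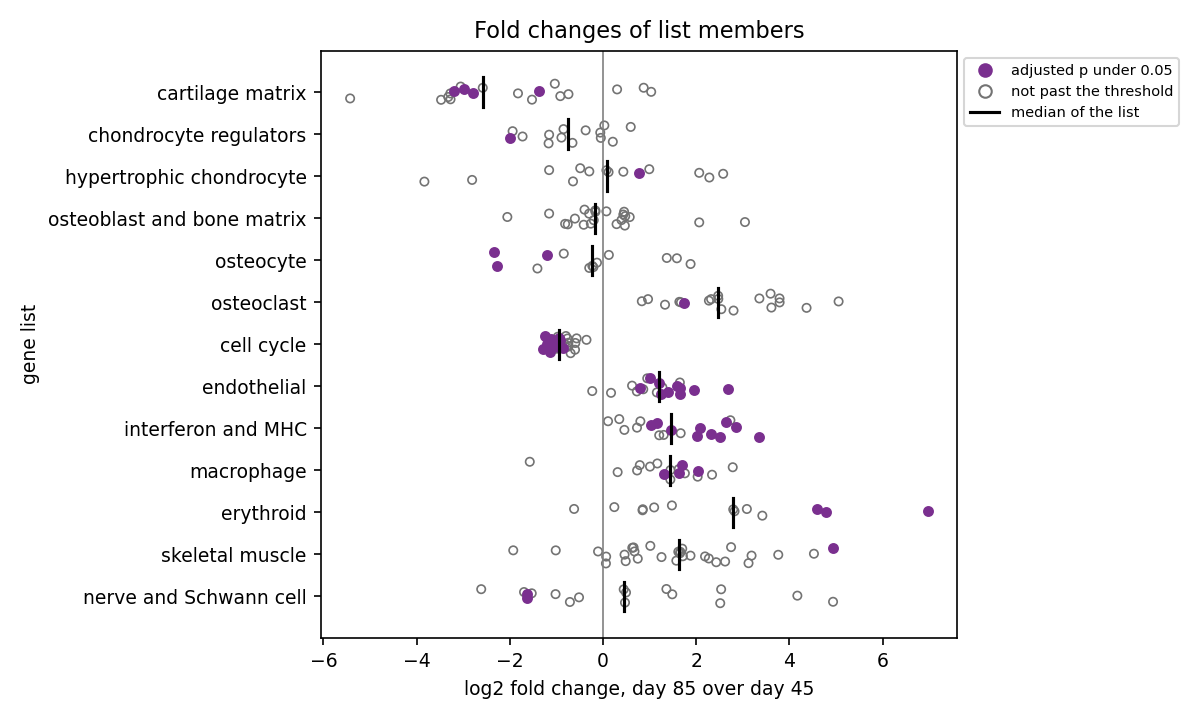
Log2 fold change (day 85 over day 45) of every tested member of 13 gene lists. Filled marks passed an adjusted p of 0.05, open marks did not, and the black bar is the list's median. Cell cycle members all lie below 0 with a median of -0.95, osteoclast members all lie above 0 with a median of 2.47, and skeletal muscle members spread widely around 1.63.

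Of 30 skeletal muscle genes, MYBPC2, a myosin-binding protein of fast fibres, passed over all genes, at 6.65 ± 1.92 CPM at day 45 and 286, 25.6 and 304 CPM at day 85 (log2 fold change 4.94, SE 0.96, adjusted p = 0.0428), and none passed when adjusted over the list alone. The list did not pass (camera adjusted p = 0.111) but did without day 85 replicate 2 (4.59e-09), where 17 members rose, day 45 replicate 1 (0.0491) or day 45 replicate 3 (0.0489). DESeq2 called 7 higher, and edgeR 0 without each library other than day 85 replicate 2. MYH3, embryonic myosin, was at 3716 ± 1362 CPM at day 45 and at 8513, 571 and 8132 CPM at day 85. Of 17 nerve and Schwann cell genes, the neuronal genes SYT1 and NEFM fell 3.11-fold and 3.10-fold (adjusted p = 0.0233 and 0.0262). Adjusted over the list alone, 3 fell and 1 rose; the median and mean were 0.44 and 0.41 while the test pointed down (camera adjusted p = 0.489). That positive median rests on day 85 replicate 2: without it the median was -0.55, with 5 members lower and 1 higher, and DESeq2 on all libraries had a median of -0.05 and called 6 lower and 1 higher. Of 20 tendon and fibrous tissue genes, KERA was the 1 that fell, 4 fell when adjusted over the list alone, and 19 had negative log2 fold changes (camera adjusted p = 0.00112; adjusted p = 0.568 with an estimated correlation; 0.0565 without day 85 replicate 1). Leaving out day 85 replicate 2 gave 3 lower, and DESeq2 called 6 lower. COL3A1 and DCN, the most abundant of them, had log2 fold changes of -0.23 and -0.24 (adjusted p = 0.562 and 0.440).

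Among the signalling lists, hedgehog was lower and Notch higher, and Wnt, BMP and FGF did not pass. In the hedgehog list SMO, the signal transducer smoothened, fell 1.55-fold (adjusted p = 0.0467), GLI3 had a log2 fold change of -0.47 (adjusted p = 0.114), 2 of 13 fell when adjusted over the list alone, and the list was lower (camera adjusted p = 0.0101; adjusted p = 0.535 with an estimated correlation). Its levels were -1.22, -0.13 and -0.86 at day 85 relative to the day 45 mean, so day 85 replicate 2 lay within the day 45 range of -0.20 to 0.12. In the Notch list the endothelial ligand DLL4 rose 3.47-fold (adjusted p = 0.0155) and the receptor NOTCH4 2.22-fold (adjusted p = 0.0372), 8 of 16 rose when adjusted over the list alone, and the list was higher (camera adjusted p = 0.0154; adjusted p = 0.494 with an estimated correlation). Of 30 Wnt genes, WNT5B and FZD4 rose 2.62-fold and 2.27-fold (adjusted p = 0.0379 and 0.0259) and SOST and FZD2 fell 5.07-fold and 1.88-fold (adjusted p = 0.0160 and 0.0200); adjusted over the list alone 2 rose and 2 fell, and the list did not pass (camera adjusted p = 0.374). TGFBR2, 1 of 33 BMP and TGF-beta genes, rose 2.29-fold (adjusted p = 0.0450) and none passed when adjusted over the list alone (camera adjusted p = 0.327). In the FGF and IGF list FGF1, SPRY4 and IGFBP7 rose 2.89-fold, 2.48-fold and 1.71-fold (adjusted p = 0.0200, 0.0259 and 0.0440), IGFBP2 fell 1.80-fold (adjusted p = 0.0449), and 6 of 25 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.292). Leaving out day 85 replicate 2 gave 1 higher and 7 lower for hedgehog, 5 and 0 for Notch, 6 and 7 for Wnt, 3 and 6 for BMP, and 8 and 2 for FGF, and leaving out each other library gave 0 or 1 per list. With DESeq2 these were 0 and 6, 8 and 1, 3 and 7, 4 and 7, and 8 and 2.

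Among named genes with at least 10 CPM in the higher age, HMCN2 had the largest rise, 59.1-fold from 1.86 to 146, 19.8 and 166 CPM (log2 fold change 5.88, SE 1.11, adjusted p = 0.0400). The rises of MYBPC2, SLC4A1, SLC4A9, PEBP4, SLA-DRA, SLA-DRB1, SLA-DRB5 and MLIP were also among the 10 largest. In the day 85 libraries SLC4A9 stood at 22.6, 2.93 and 20.4 CPM, PEBP4 at 39.7, 11.7 and 32.9 and MLIP at 18.8, 9.80 and 20.7. Like HMCN2 and MYBPC2, these were lowest in replicate 2, which also had the smallest share of skeletal muscle counts. SLC4A1 and the SLA genes were not lowest there. SLA-DRB1, an MHC class II beta chain, rose 9.53-fold to 46.0 ± 3.20 CPM with the smallest adjusted p of all genes (0.00351), and its counts may be shared with SLA-DRB5. The largest fall was that of the keratin KRT13, 35.4-fold from 13.4 ± 5.80 to 0.370 ± 0.403 CPM (log2 fold change -5.14, SE 0.82, adjusted p = 0.0287). PNOC, the precursor of the neuropeptide nociceptin, fell 13.6-fold (adjusted p = 0.0432) and STRA6, a retinol transporter, 9.33-fold (adjusted p = 0.0213). PAPSS2, which makes the sulfate donor used for cartilage proteoglycans, fell 7.18-fold from 407 ± 57.1 to 56.7 ± 34.0 CPM (adjusted p = 0.0270). The falls of CHADL, PIANP, HAPLN1, TMEM151A and GAS2 were also among the 10 largest. All of these genes were called without day 85 replicate 2 as well, where the log2 fold changes of KRT13, PNOC and PAPSS2 were -6.46, -4.94 and -3.44. For KRT13 it was -4.55 without day 85 replicate 3, and for HMCN2 7.16 without day 45 replicate 3 (adjusted p = 0.07).

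Annotation terms carried by the table were tested for enrichment. Among genes that rose at least 2-fold, antigen processing and presentation held 15 of its 52 background genes against 1.5 expected (one-sided Fisher's exact test, adjusted p = 7.25e-08) and angiogenesis 27 of 236 against 6.7 (adjusted p = 1.28e-06). Among genes that fell at least 2-fold, mitotic cell cycle held 22 of 470 against 6.5 (adjusted p = 0.000267) and chromosome segregation 13 of 179 against 2.5 (adjusted p = 0.000439). Neuronal terms were enriched among falls too: synapse held 14 of 269 against 3.7 (adjusted p = 0.00362) and neuron projection 15 of 324 against 4.5 (adjusted p = 0.00625). In all, 108 of 4164 Gene Ontology terms were enriched among rises and 65 among falls, and 23 and 0 of 261 KEGG pathways. Apart from complement and coagulation cascades, pertussis and hematopoietic cell lineage, each of the 23 held SLA-DRA with other MHC class II genes. They are therefore largely 1 shared group of genes and not separate results. KEGG terms were tested on 3543 annotated genes, of which 43 had fallen at least 2-fold; 7 terms among falls had an unadjusted p under 0.05.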

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

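The muscle score, with either correlation, and the removal of the mitochondrial genome were chosen after seeing the data. All 986 called genes kept their sign under every alternative that tested them. RLE, upper-quartile and total-count scaling, no filter, the stricter filter, limma-voom, limma-trend on log2(FPKM + 1), and leaving out the 20 most abundant genes or the mitochondrial genome gave 869 to 1112 genes, and shared 707 to 986 with the 986. DESeq2 gave 3834 genes (2064 higher, 1770 lower), which included all 986, and gave no adjusted p for 4005 of 20451 genes. The muscle score as a covariate gave 2694 (1600 higher, 1094 lower). A pseudocount of 0.1 on FPKM gave 357 higher and 516 lower, no FPKM filter gave 456 (190 higher, 266 lower), and the test against a 1.5-fold change, which asks for more than a difference from 0, gave 45 (38 higher, 7 lower). Leaving out single libraries gave 0 to 3412 genes, 0 to 1884 higher and 0 to 1528 lower, the highest without day 85 replicate 2 and the others at 118 or fewer; a fit of 5 libraries has fewer residual degrees of freedom, yet removing day 85 replicate 2 raised the count. Apart from the loss of a library, the cause of these shifts was not tested. Of the 20 lists called, 0 were called with an estimated correlation, where cartilage matrix, osteoclast and endothelial had adjusted p = 0.535 and cell cycle and interferon 0.494. Fry called 6: cell cycle (0.0338), interferon (0.0338), endothelial (0.0414), Notch (0.0338), adipocyte (0.00253) and mandible patterning (0.0399). It left cartilage matrix at 0.0832 and osteoclast at 0.150. RLE scaling and the stricter filter kept 20 of 20, and single libraries left out kept 15 to 20; the cartilage matrix, osteoclast, cell cycle, endothelial and interferon lists held in each. The muscle score kept 19 of 20 with the preset correlation, losing HOX (0.119) and gaining mineralization (0.0437), and 0 with an estimated one (cartilage matrix, osteoclast and cell cycle 0.37, endothelial 0.429, interferon 0.376). The hypertrophic and osteoblast lists passed under none. With no fold minimum, 163 rather than 108 Gene Ontology terms were enriched among rises and 98 rather than 65 among falls, from longer gene lists, and 24 KEGG terms rather than 23. Of 121 named genes, 85 were called. RLE kept 84, DESeq2 85, the muscle covariate 84, and without day 85 replicate 2 all 85 were kept, while leaving out any other library kept 0 to 17. MYH3, itself in the muscle score, turned to a log2 fold change of -0.92 with that score as a covariate. At the depth of these libraries the simulated test missed most 2-fold changes, so genes not called are not shown to be unchanged.

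The replicate numbers are shared between the ages. Deviations from the age means correlated at 0.013, 0.25 and 0.04 for the same-numbered pairs, and not every library correlated best with its own number. Pairing by number was thus not seen, but so few libraries cannot exclude a shared origin or batch. With the number as a replicate block, 682 genes were called (465 higher, 217 lower), 508 of them among the 986. Of the 20 lists, 19 kept their call (the HOX list moved to an adjusted p of 0.101), and the skeletal muscle list passed at 0.00927. Of the 85 called named genes, 55 passed. The block called 12 of 19 osteoclast genes higher rather than 1. It called 12 of 32 cell cycle genes lower rather than 16, and 2 of 19 cartilage matrix genes lower rather than 4.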

Other observations

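All tests of explanations here were chosen after the result was seen. Further gene groups changed with age. Adipocyte genes were higher as a list (camera adjusted p = 7.88e-05; adjusted p = 0.391 with an estimated correlation), with 4 of 9 members rising and 7 when adjusted over the list alone. The adipogenic transcription factors CEBPA and PPARG rose 3.22-fold and 3.16-fold (adjusted p = 0.0372 and 0.0181). The lipid droplet gene PLIN1 went from 2 counts to 134, a ratio of 70.7 with a 95% counting interval of 19.2 to 590, and PCK1 from 2 to 84, a ratio of 44.3 (11.9 to 372). All day 45 counts of both genes lay in replicate 1, and the intervals leave out the spread between libraries. Immediate early genes were higher (camera adjusted p = 0.00207; adjusted p = 0.535 with an estimated correlation; 0.0629 without day 85 replicate 2), with EGR3, FOS, DUSP1 and KLF6 up 6.05-fold, 6.02-fold, 2.69-fold and 1.43-fold, and 7 of 17 members rising when adjusted over the list alone. Nuclear genes of oxidative phosphorylation were slightly higher, with 25 of 27 log2 fold changes above 0 and a median of 0.39 (camera adjusted p = 5.71e-05; adjusted p = 0.568 with an estimated correlation). SDHA and SDHD rose 1.68-fold and 1.63-fold, and 7 rose when adjusted over the list alone. Secretory and collagen-processing genes were lower (camera adjusted p = 0.000505; adjusted p = 0.581 with an estimated correlation): PCOLCE2 fell 2.19-fold and SEC23A 1.64-fold, and 4 of 24 fell when adjusted over the list alone. The level of that list in day 85 replicate 2 (-0.06) lay within the day 45 range of -0.15 to 0.12. Leaving out day 85 replicate 2, edgeR called 8 adipocyte and 13 oxidative phosphorylation genes higher, 5 immediate early genes higher and 2 lower, and 12 secretory genes lower. Leaving out each other library, it called 0 or 1 adipocyte, 0 to 3 immediate early, and 0 oxidative phosphorylation and secretory genes. DESeq2 on all libraries called 8, 10 and 7 higher and 9 secretory genes lower, for adipocyte, oxidative phosphorylation and immediate early genes in turn.

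Genes of an early fetal program were lower (camera adjusted p = 0.00984; adjusted p = 0.494 with an estimated correlation; 0.0821 without day 85 replicate 2). MEST fell 2.78-fold from 274 ± 33.5 CPM and IGF2BP1 2.09-fold (adjusted p = 0.0211 and 0.0462), and 3 of 12 fell when adjusted over the list alone. In the list of mandible patterning genes, TBX22 fell from 1.40 to 0.158 CPM (adjusted p = 0.0247) and LHX6 rose 3.98-fold (adjusted p = 0.0433). Adjusted over the list alone, 4 of 20 fell and 1 rose. That list was lower (camera adjusted p = 0.0363; adjusted p = 0.494 with an estimated correlation) but missed the threshold without day 45 replicate 2 (0.0628), day 85 replicate 1 (0.0505) or day 85 replicate 2 (0.130). HOX genes were higher as a list (camera adjusted p = 0.0363, or 0.581 with an estimated correlation) with 0 of 7 past the threshold in edgeR and 3 at an unadjusted p under 0.05. DESeq2, run on all genes with a count, called 1 of 23 members, counted whether or not they got an adjusted p. The HOX list missed the threshold without the same libraries (0.138, 0.0565 and 0.129) and with a skeletal muscle score as a covariate (0.119). HOXD4 was at 2.88 ± 0.876 and 5.76 ± 0.376 CPM and HOXD3 at 1.76 ± 0.838 and 3.74 ± 1.01 CPM. Neutrophil genes were higher (camera adjusted p = 0.0199; adjusted p = 0.535 with an estimated correlation) with 0 of 13 past the threshold in edgeR (4 at an unadjusted p under 0.05, and 2 of 15 called by DESeq2) and 2 when adjusted over the list alone, and missed the threshold without day 45 replicate 2 (0.128) or day 85 replicate 2 (0.0821). ELANE, a neutrophil granule protease, was at 4.37 and 5.30 CPM. The lymphoid list did not pass (camera adjusted p = 0.0791): CD4 and BLNK rose 4.63-fold and 2.19-fold, and it passed without day 45 replicate 3 (0.0212) or day 85 replicate 3 (0.0310). Lists that did not pass were superficial articular cartilage (camera adjusted p = 0.791, median -0.23 and mean 0.02; VIT rose 4.15-fold), matrix proteases (0.499; TIMP4 rose 3.71-fold from 0.523 CPM), glycolysis and hypoxia (0.385; ADM rose 2.53-fold), epithelium (0.535, median 0.38 and mean -0.21; KRT15 fell from 4.20 to 0.0955 CPM, with a log2 fold change of -5.38, and of -4.33 without day 45 replicate 1, and CLDN7 rose 8.41-fold) and the mitochondrial genome (0.489, test downward with a median of 0.19 and a mean of 1.43), though the last passed downward without day 45 replicate 3 (2.75e-05), and its median ran from -1.75 to 0.44 over the libraries left out. Leaving out day 85 replicate 2, 5 early fetal genes fell, 3 mandible patterning genes rose and 5 fell, 1 neutrophil gene rose, and the epithelial list had a median of -0.52 with 2 higher and 3 lower; leaving out each other library gave 0 or 1 in these lists.

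The day 85 libraries differed in makeup. Over members, the mean log2 level in replicate 2 minus that of replicates 1 and 3 was 2.47 for cartilage matrix (SE 0.495, 19 genes), 2.32 for osteoclast (SE 0.206), 1.75 for nerve and Schwann cell genes (SE 0.468), 0.772 for osteoblast genes (SE 0.130), -0.277 for endothelial genes (SE 0.0796) and -3.80 for skeletal muscle (SE 0.111). Dilution by muscle RNA in replicates 1 and 3 would lower genes that muscle fibres lack alike. Yet cartilage matrix lay 1.70 (SE 0.512) and osteoclast 1.55 (SE 0.244) above the osteoblast list, the nearest of the osteoblast, cell cycle and tendon lists. Nerve genes lay 0.98 above it (SE 0.486), just over 2 SEs, so for them this rests on little. All SEs of this paragraph are over genes, which are correlated within lists, and not over libraries. They understate the uncertainty of a difference that rests on 1 day 85 library. A larger total count would set replicate 3, whose total is nearer that of replicate 2 than that of replicate 1, beside replicate 2. Over the 55 members of the cartilage, osteoclast and nerve lists, replicate 2 lay 2.16 above replicate 3 and replicate 3 lay 0.0816 above replicate 1, steps that differ by 2.08 (SE 0.292). These comparisons replaced one with endothelial genes, which muscle tissue carries, and one with thinned counts, whose outcome library scaling fixes. Whether replicate 2 was a day 45 library was not decided by the genes called without it: for the 3349 of these 3412 that were also tested with all libraries, its median place was 0.477 on a scale from 0 at day 45 to 1 at replicates 1 and 3. A count of lists, chosen after that, argues against it: in 12 of the 17 lists called without it, it lay beyond all 3 day 45 libraries on the day 85 side. Across all genes it lay no nearer its own age than day 45: the chi-square per degree of freedom was 118.5, 143.9 and 147.9 to the day 45 libraries and 188.2 and 147.8 to replicates 1 and 3, against 20.2 to 49.6 among the day 45 libraries. A candidate explanation, for which the design gives no group and which was not tested, is that the dissected pieces held different shares of cartilage, ossification front, muscle and nerve.

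Counts on the mitochondrial genome alternated between genes. COX1 had 257383 counts in day 85 replicate 2 and 301, 200, 0, 0 and 0 in the others, ATP6 had 102420 and 92581 in day 45 replicates 1 and 2 and 0 elsewhere, and CYTB had 13 counts in day 85 replicate 1 and 81674 in replicate 3. A difference in mitochondrial RNA content would move these genes together, yet in 4 of the 6 pairs of libraries of one age, genes that reach 1000 CPM moved over 2-fold in opposite directions. The CPM of all genes of the mitochondrial genome together differed by 5.80-fold between the highest and the lowest library. Each of the 5 genes that reach 1000 CPM differed by at least 2850-fold on CPM plus 1. These genes had already been seen near 0 in some library, so a wider range than that of the sum followed from their choice. The comparison therefore cannot decide whether the counting placed reads on different mitochondrial genes in different libraries. No other biological explanation was tested. Because of this alternation no fold change of a mitochondrial gene is given.

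The rise of antigen presentation and vessel genes and the fall of cell cycle genes ran through all 3 day 85 libraries, with list levels of 1.63, 1.89 and 1.07 for interferon and antigen presentation. Muscle RNA as the whole cause is argued against by the muscle score. With it as a covariate, mean log2 fold changes over all members went from 1.62 to 1.64 for interferon, 1.17 to 1.06 for endothelial and -0.932 to -0.857 for cell cycle (SEs of 0.215, 0.149 and 0.039 with the score), so a share of at least 0.91 was left. As lists, the largest adjusted p of these with the score was 6.55e-08 with the preset correlation, but 0.429 with an estimated one, which left none of them called without the score either. The mean log2 fold changes of the osteoclast and tendon lists lay 3.21 apart (SE 0.338). Osteoclast levels were 1.52, 3.84 and 1.51 in day 85 replicates 1, 2 and 3, so part of that gap rests on replicate 2. The gap argues only against a lower share of cartilage cells that raised all other cell types alike. A lower share of cartilage cells with unequal changes of other cell types was not tested and stays open. The SEs of this paragraph are likewise over correlated genes and not over libraries, so they understate the uncertainty. Growth of vessels and of immune and marrow cells with age, a difference the design names, stays open as a hypothesis and was not tested apart from other differences between the ages. Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes as the real one (986), itself, and the highest of the others called 5; 10 splits are too few for a share under 0.05.

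The Y-linked genes DDX3Y and USP9Y had 3599 and 1280 counts in day 45 replicate 1, 3142 and 1054 in day 45 replicate 2 and 2681 and 1221 in day 85 replicate 3, and at most 2 counts in each of the other libraries. By these counts each age held libraries of both sexes, and so of more than 1 animal. Sex was spread unevenly between the ages and was not a factor in any fit, so its part in the differences was not tested.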
